A study of Mus musculus with 6 samples.

How the data were processed

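Inguinal lymph nodes of 3 perampanel-treated and 3 control SJL mice were meshed to cell suspensions on day 3 after EAE induction, and poly(A) RNA was made into libraries with the NEBNext Ultra II RNA kit, per the labels' protocols. The kit under this name does not mark strand. The series holds 1 table of 23307 genes. For the 6 samples it gives size-factor-normalized signal, that is read counts divided by 1 factor per sample, as deposited by the authors. The authors' deposited table also holds their log2 fold changes with standard errors, a Wald statistic (a score), p-values and adjusted p-values, and the mean normalized signal per gene. DESeq2 and DESeq, without versions, and the genome build GRCm38 are named per the submitters' processing notes. The aligner and the counting tool are not given in the sources used here. No other per-sample column was present, and each column was tied to its sample by the name in the labels' description. The authors' deposited log2 fold changes were taken as perampanel over control from the sample columns, and the sign of the deposited score is opposite to the fold for all 19321 genes that have one.

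Every non-zero value in a sample was a whole multiple of that sample's smallest value (100% within a tolerance of 1e-06), which gave back whole read counts in all 6 samples. In perampanel 2 that smallest value is 1.01, too close to 1 for an automatic check of such steps to accept it, and its reads were recovered in the same way as the others. The recovered reads served for the depths and for count tests as alternatives only. Libraries held 2036072, 2208589 and 2182424 reads in controls 1 to 3 and 2003726, 1998488 and 1779724 in perampanel 1 to 3. The floor of 3 reads is 1.36 to 1.69 CPM, and it covers counting error only. Reads carry no molecular identifiers. Chi-square per degree of freedom between libraries of 1 group was 1.57 to 1.82, so no pair agreed within sampling noise and all 6 were counted as separate samples.

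The gene test, lists, alternatives and rule for named genes were fixed before the data were examined. The design foresaw raw counts or normalized values, and as the values are normalized, the test planned for that case was used. Genes with a mean of at least 10 normalized counts (9076 of 23307) were tested with limma-trend (limma 3.58.1, R 4.3.3) on log2(value + 1), with treatment as the only factor and all 6 samples. P-values were adjusted by Benjamini-Hochberg and called under 0.05. Fold changes are on the log2(value + 1) scale, and for genes with few reads their size can differ from that of a count test in either direction. Rrm2 was at -2.49 against -2.15 by DESeq2 on recovered reads, and Ccna2 at -2.18 against -1.67. Tyms was at -1.65 against -1.69. The table of 38 gene lists held 729 genes, of which 416 were tested. Lists with at least 5 tested genes (27) were tested with camera at a preset correlation between genes of 0.01, and again with the correlation estimated and with fry. Marker scores were means over markers of the log2 value minus its mean over libraries, compared by a two-sided exact permutation test, for which 3 against 3 allows no p below 0.1.

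Named genes were the 10 called genes with the largest rise and the 10 with the largest fall among those with a mean of at least 50 and no overlap between groups, up to 3 called members of smallest p from each list that passed or held 2 or more called members, and, whatever their values, the AMPA receptor genes Gria1 to Gria4, S1pr1, Klf2, Ccr7 and Cd69. Some genes that the rule takes are not reported here. Other members quoted as examples of a list, and Cd3e, Cd79a, Ighm, Xist, Ddx3y and Uty, were chosen after their values were seen. Gene positions are from GENCODE mouse release 21 (GRCm38), in which 22086 gene names matched once, 44 more than once and 1177 not at all. The table writes a point for a hyphen, as in H2.Aa. Without strand, reads of overlapping and antisense genes cannot be told apart.

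Alternatives were quantile normalization, filters on low values, the replicate number as a block, each library left out in turn, DESeq2 1.42.0 and limma-voom on recovered reads, pseudocounts of 0.1 and 10, other thresholds, a robust variance prior and the leading residual component as a covariate. Added after seeing the data were the edgeR 4.0.16 quasi-likelihood test on recovered reads, TMM scaling and thinning of all libraries to 1779724 reads. The edgeR test called 107 of 9175 genes, 99 of them among the 100. A swap to DESeq2 size factors for marker scores had no effect to measure, since the deposited values carry size factors, and TMM took its place.

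The tests were tried on data simulated for this comparison, with 8985 genes tested and known changes. Limma recovered 40.9% of genes changed by 0.5, 90.9% of those changed by 1 and 100% of those changed by 2 on the log2 scale, and 10 of its 162 calls were false. Camera at its preset correlation called the changed list and 0 of 20 unchanged lists. The simulated result does not vouch for camera p-values of the real lists, whose genes can be more strongly correlated. The estimated correlation was 0.52 in the cell cycle list and 0.45 in the interferon-gamma list, but 0.00012 in the glucocorticoid list. Splits of the real samples that mixed the groups still gave 3 to 11 called lists. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures with matplotlib 3.10.9.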

Results

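RNA-seq was performed on cells of inguinal lymph nodes, which drain the flank, taken from SJL mice on day 3 after induction of experimental autoimmune encephalomyelitis (EAE), a mouse model of multiple sclerosis. The 2 groups were 3 mice treated with perampanel, an antiseizure drug that blocks AMPA-type glutamate receptors, and 3 control mice, so the labels do name 3 animals per group. Each library held between 1779724 and 2208589 reads assigned to genes, and 13677 to 14387 genes were detected. Every perampanel library (1779724 to 2003726 reads) was shallower than every control library (2036072 to 2208589 reads). Mitochondrially encoded mRNAs took 9.84% to 10.3% of the reads in controls and 10.3% to 10.8% under perampanel (n = 3 each). The libraries were rich in T cell transcripts: Cd3e, a chain of the T cell receptor complex, averaged 2263 normalized read counts, against 28.4 for Cd79a, a signalling chain of the B cell receptor, and 437 for Ighm, the heavy chain of IgM.

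The comparison of perampanel with control asks how AMPA receptor blockade alters gene expression in the draining lymph node. Under perampanel 9 of 27 tested cell cycle genes fell and 5 of 10 genes of the glucocorticoid response rose by limma. Both lists were called by camera at its preset correlation, with adjusted p = 0.224 for the cell cycle and 0.0456 for the glucocorticoid list with an estimated correlation. Rrm2, which makes deoxynucleotides for DNA synthesis, fell from 99.1 ± 17.9 to 22.2 ± 16.7 normalized read counts. Plaur, the urokinase receptor, rose from 132 ± 28.7 to 328 ± 110 (SD, n = 3 each). Of 9076 genes tested, 100 changed by limma at a Benjamini-Hochberg adjusted p under 0.05, 38 of them higher and 62 lower. The genes that fell had a median size of 0.97 on the log2 scale and those that rose 0.42, and among genes with a change of at least 1 there were 30 lower and 1 higher, Plaur. The count was 44 without control 1 (19 higher and 25 lower) and 55 without control 2 (16 and 39), of which 42 and 50 were among the 100. With thinned libraries 23 were higher and 59 lower, with quantile normalization 25 and 53, and with TMM scaling 43 and 58. When only genes with a mean of at least 50 normalized read counts were tested, 44 were higher and 48 lower. The excess of falls was thus small among these genes. DESeq2 called 50 genes, 28 higher and 22 lower, among 3759 genes to which it gave an adjusted p.

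**Figure D1:**
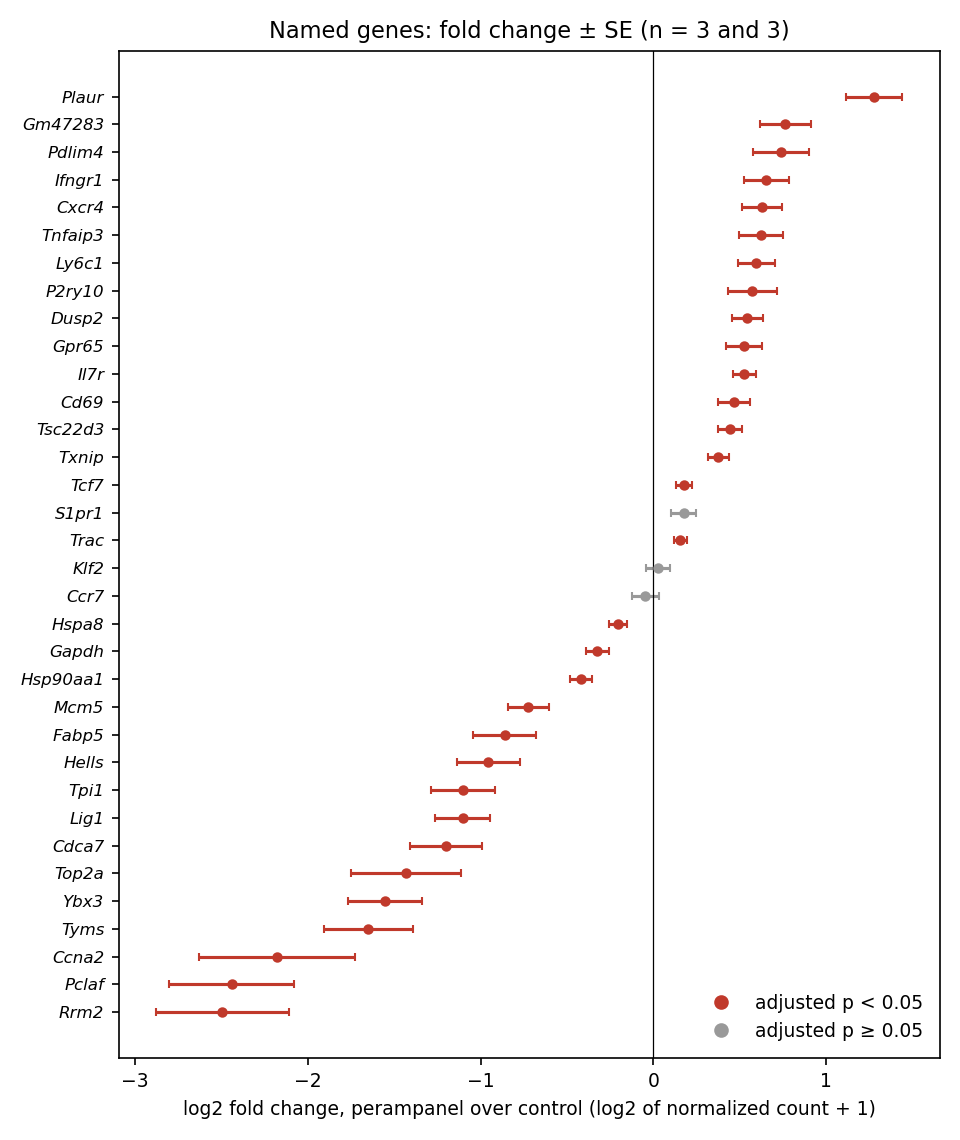
Log2 fold change of perampanel over control for tested named genes, on the log2(normalized read count + 1) scale, with bars of 1 SE (n = 3 and 3). Red points passed an adjusted p of 0.05 and grey points did not. Values run from -2.49 for Rrm2 to 1.28 for Plaur.

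Genes of nucleotide supply, DNA replication and mitosis were among the cell cycle genes that fell in nodes of perampanel-treated mice. Rrm2 (chromosome 12, 24708241 to 24714146, GRCm38, protein-coding) fell by 2.49 ± 0.38 on the log2 scale (SE, limma adjusted p = 0.000623). Tyms, thymidylate synthase (chromosome 5, 30058202 to 30073617), fell by 1.65 ± 0.26, from 46.4 ± 5.40 to 14.3 ± 3.61 normalized read counts. Mcm5, a subunit of the replicative helicase, fell by 0.72 ± 0.12, from 163 ± 15.1 to 98.0 ± 0.828. The cyclin Ccna2 (-2.18) and the topoisomerase Top2a (-1.43) fell too. Outside the list, the falls included Pclaf, a partner of the replication clamp PCNA (-2.44), Cdca7 (-1.20), the DNA ligase Lig1 (-1.10) and the chromatin remodeller Hells (-0.95). Of 27 tested members of the cell cycle list, 9 fell and none rose by limma over all genes, 21 fell when adjusted over the list alone, and all 27 had a negative fold change. Their mean was -1.21 ± 0.13 (SE over genes), and the list was lower by camera with an adjusted p of 7.39e-31, with adjusted p = 0.224 with an estimated correlation. Per library, the list mean relative to all libraries was 0.93, 0.42 and 0.46 in controls and 0.13, -0.33 and -1.61 under perampanel, without overlap, and an exact permutation test gave p = 0.1, the smallest that 3 against 3 allows. Without perampanel 3, the shallowest library, the list mean was -0.71. Rrm2 was then at -1.66, Top2a at -0.72, Ccna2 at -1.19 and Pclaf at -1.62. Top2a lost its call without control 1 (-1.24) and without control 2 (-1.59), and Ccna2 without control 2 (-2.26). Of the genes named here DESeq2 called only Mcm5: Pclaf (-2.10) and Top2a (-1.16) did not pass, and it gave Rrm2, Ccna2, Tyms, Cdca7, Lig1 and Hells no adjusted p.

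**Figure D2:**
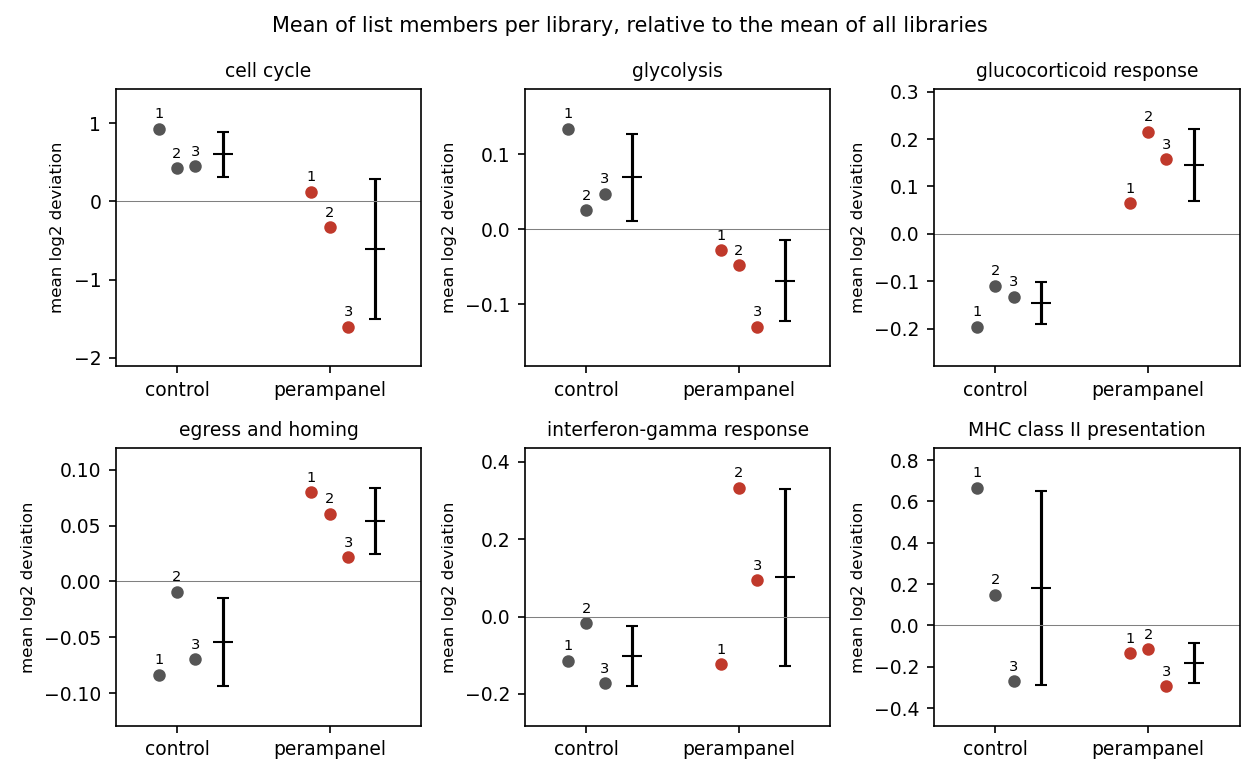
Mean over list members of the log2 normalized read count minus the gene's mean over all libraries, per library, for 6 gene lists, with bars of the group mean and 1 SD (n = 3). In the cell cycle list the controls lie between 0.42 and 0.93 and the perampanel libraries between -1.61 and 0.13.

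Genes of the glucocorticoid response were higher under perampanel. Il7r, the receptor subunit for the survival cytokine IL-7 (chromosome 15, 9505788 to 9530176), rose from 1438 ± 144 to 2074 ± 246 normalized read counts (log2 0.53 ± 0.07, SE, limma adjusted p = 7.12e-05). Tsc22d3, the leucine zipper protein induced by glucocorticoids, rose by 0.44 ± 0.07 and Txnip, an inhibitor of thioredoxin, by 0.38 ± 0.06. The chemokine receptor Cxcr4 and Ddit4, an inhibitor of mTORC1 signalling, rose by 0.63 and 0.32. These 5 of 10 tested members rose and none fell, also 5 adjusted over the list alone, and the others were Per1 at 0.36, Nfkbia at 0.17, Sgk1 at 0.12, Dusp1 at 0.12 and Fkbp5 at -0.15. The list was higher by camera (mean 0.29 ± 0.07, adjusted p = 9.56e-12), and it was the 1 list of 27 that held with an estimated correlation (adjusted p = 0.0456). It did not pass fry, which tests the list by itself (adjusted p = 0.0511). All 3 perampanel libraries lay above all 3 controls in the list mean (exact permutation p = 0.1).

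Genes of lymph node egress and homing moved in part. Cxcr4, the receptor for CXCL12 (chromosome 1, 128588199 to 128592293), rose from 130 ± 15.4 to 201 ± 18.5 normalized read counts (log2 0.63 ± 0.12, limma adjusted p = 0.00383). Cd69, which holds lymphocytes in tissue by removing the sphingosine-1-phosphate receptor S1P1 from the surface (chromosome 6, 129267325 to 129275436), rose from 215 ± 18.3 to 298 ± 8.89 (log2 0.47 ± 0.09, adjusted p = 0.00631). S1pr1, which encodes S1P1, the receptor that guides lymphocytes out of the node, was at 660 ± 13.4 and 748 ± 85.0 and did not pass the limma test (log2 0.18, 95% interval 0.03 to 0.32, adjusted p = 0.395). Klf2, the transcription factor that drives S1pr1, had a log2 fold change of 0.03 (95% interval -0.11 to 0.17) and Ccr7, the receptor for entry and positioning in the node, -0.05 (-0.21 to 0.12). Of 17 tested members 2 rose, Cxcr4 and Cd69, and 5 rose adjusted over the list alone, Gpr183 and Itga4 among them. The list was higher by camera (mean 0.11, median 0.05, adjusted p = 0.00126), with adjusted p = 0.224 with an estimated correlation. Cd69 lost its call without control 2 (log2 0.40).

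**Figure D3:**
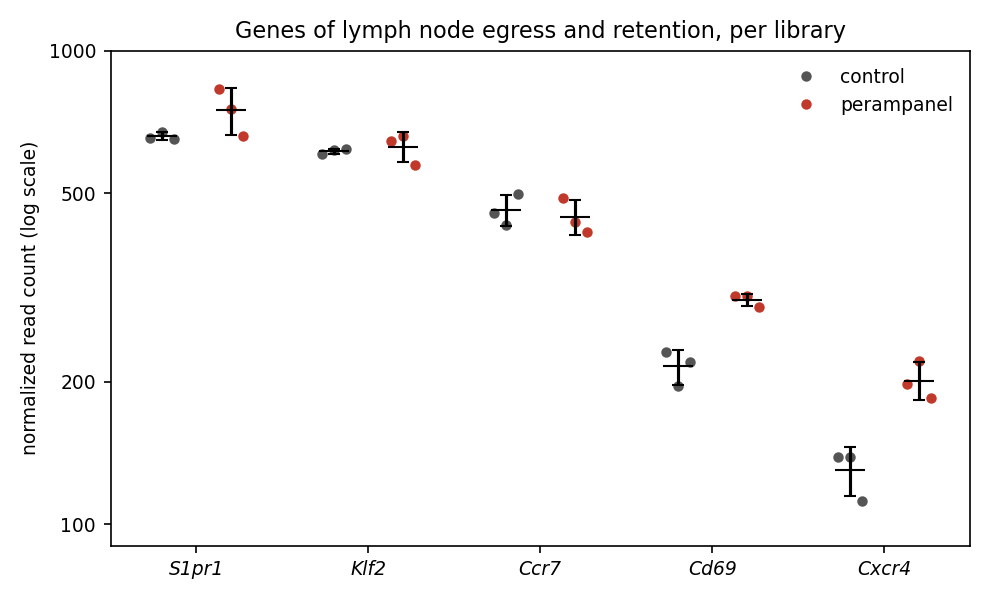
Normalized read counts per library, on a log axis, of 5 genes of lymph node egress and retention, with the group mean and 1 SD (n = 3 per group). Cd69 and Cxcr4 show higher values in every perampanel library than in any control, and Klf2 and Ccr7 overlap between the groups.

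Transcripts of the AMPA receptor itself, the drug's known target, were at the limit of detection. Gria1 had 0 reads in the 3 control libraries and 3 in the 3 perampanel libraries, 1 in each. Gria2 had 8 and 6 reads, Gria3 12 and 14, and Gria4 2 and 1, out of 6427085 control and 5781938 perampanel reads. A floor of 3 reads corresponds to 1.36 to 1.69 CPM, and for counting error alone a difference in these genes was not detectable at this depth. Only 2 members of the list of ionotropic glutamate receptors and partners were tested, the vesicle fusion ATPase Nsf (678 reads in all) and the kainate receptor subunit Grik4 (94 reads), with log2 fold changes of 0.10 and 0.20 that did not pass. None of the 10 tested genes of glutamate transport and metabolism passed, over all genes or adjusted over the list alone, where the count was 0 (mean -0.08, camera adjusted p = 0.195).

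T cell genes changed little in size. Trac, the constant region of the T cell receptor alpha chain, rose by 0.16 and the T cell transcription factor Tcf7 by 0.18 on the log2 scale by limma. Of 19 T cell markers 3 rose, these among them, and 5 passed adjusted over the list alone, where Lef1 (0.16) passed as higher and Cd8a (-0.36) as lower. The marker list was higher by camera (mean 0.04, adjusted p = 0.00527), with adjusted p = 0.401 with an estimated correlation, and lost the call without control 1 (mean 0.011) and without perampanel 1. The T cell receptor signalling list had 1 of 21 members higher and 1 adjusted over the list alone (mean 0.09, camera adjusted p = 0.00350, and adjusted p = 0.401 with an estimated correlation), and lost its call without control 1 (mean 0.05). Trac and Tcf7 lost their calls without either control 1 or 2 or perampanel 1 or 3 (0.12 to 0.16 and 0.14 to 0.18). In the T cell activation list, 1 of 20 members rose, Cd69, and 5 passed adjusted over the list alone, with 3 higher and 2 lower, and the list was not called by camera (mean -0.08, adjusted p = 0.892). Egr1, an early gene of receptor stimulation, was at 0.43, and Batf and Myc, factors of T cell differentiation and growth, were at -0.68 and -0.37.

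Genes of regulatory T cells were lower as a list. Foxp3, which specifies these cells, was at 53.5 ± 10.1 normalized read counts in controls and 34.6 ± 11.3 under perampanel (log2 -0.65, limma adjusted p = 0.253), and Ikzf2 was at -0.98. None of 12 tested members passed over all genes, and 3 passed adjusted over the list alone, Foxp3 and Ikzf2 as lower and Tnfrsf18 as higher. The list mean was -0.32 (camera adjusted p = 0.0220, and adjusted p = 0.401 with an estimated correlation). It was -0.14 without perampanel 3 and -0.50 without perampanel 1, and the call was lost without perampanel 3 and without control 2.

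Interferon-induced genes were higher as lists but uneven between mice. Gbp2, a GTPase of host defence, was at 221 ± 27.8 normalized read counts in controls and 329 ± 106 under perampanel (log2 0.53, limma adjusted p = 0.0581), and Igtp and Iigp1, of the same kind, were at 0.36 and 0.54. Of 19 tested genes of the interferon-gamma response none passed over all genes and 7 rose adjusted over the list alone (mean 0.20, camera adjusted p = 6.70e-06, and adjusted p = 0.401 with an estimated correlation). The mean was 0.087 without perampanel 2 and 0.31 without perampanel 1. Among 20 interferon-stimulated genes none passed over all genes and 1 passed adjusted over the list alone (mean 0.19, camera adjusted p = 0.00402, and adjusted p = 0.401 with an estimated correlation). That list lost its call without perampanel 3 (mean 0.035) and had a mean of 0.34 without perampanel 1.

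Antigen presentation genes were lower in the mean, with most of the spread among controls. The MHC class II chain gene H2.Aa was at 87.3 ± 50.2 normalized read counts in controls and 44.2 ± 7.62 under perampanel (log2 -0.83, limma adjusted p = 0.116), and Cd74, the invariant chain, was at -0.76. None of 9 tested members passed over all genes and 3 fell adjusted over the list alone, H2.Aa, Cd74 and H2.Ab1. The list mean was -0.36 and its median -0.08 (camera adjusted p = 0.0161, and adjusted p = 0.401 with an estimated correlation). It lost its call without control 1 (mean -0.12) and without perampanel 3 (-0.31), and the mean was -0.59 without control 3. Markers of B cells, which carry these genes at high level, had a mean of -0.24, with library values of 0.37, 0.32 and -0.32 in controls and 0.01, -0.09 and -0.28 under perampanel, and the list was not called by camera (adjusted p = 0.546). Markers of dendritic cells, which also carry these genes, had a mean of -0.18 and were not called by camera (adjusted p = 0.406). Their library values were 0.10, 0.033 and 0.13 in controls and -0.093, -0.051 and -0.12 under perampanel, without overlap. The 5 tested were Bst2, Ccr9, Irf8, Cacnb3 and Clec10a, of which 3 had a negative and 2 a positive fold change. Zbtb46, Flt3, Itgax and Xcr1 averaged only 0.47, 1.32, 0.80 and 0.52 normalized read counts, so this score is no measure of dendritic cell number.

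A few glycolytic and heat shock genes fell. Tpi1, triosephosphate isomerase, fell by 1.10 ± 0.18, from 91.2 ± 20.8 to 41.9 ± 8.80 normalized read counts, and Gapdh fell by 0.32 ± 0.07 (SE, limma). They were the 2 called of 18 tested glycolysis genes, with 5 that fell adjusted over the list alone, among them Pgk1 (-0.28) and Pgam1 (-0.39). The list mean was -0.14 (camera adjusted p = 0.00301, and adjusted p = 0.333 with an estimated correlation). Of 29 genes of oxidative phosphorylation none passed, with 0 adjusted over the list alone (mean -0.07, camera adjusted p = 0.00841, and adjusted p = 0.401 with an estimated correlation), and the list call was lost without control 1 (-0.05). In the list of dissociation and immediate early genes, which respond to tissue handling, 2 of 13 fell, the chaperones Hsp90aa1 (-0.42) and Hspa8 (-0.20), and 3 passed adjusted over the list alone, with Egr1 as higher (mean -0.06, camera adjusted p = 0.0495, and adjusted p = 0.401 with an estimated correlation). That list lost its call when control 2, control 3, perampanel 1 or perampanel 3 was left out. Its mean ran from -0.0031 without perampanel 1 to -0.13 without perampanel 2. DESeq2 gave Tpi1 no adjusted p. Gapdh lost its call without control 1 (-0.23) and Hspa8 under every omission except perampanel 3 (-0.17 to -0.22) and under TMM scaling (-0.20). Gapdh, Tpi1 and the heat shock genes have near-identical pseudogenes in the genome, so their counts are uncertain where reads could be split.

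After Plaur, the largest rises among genes with a mean of at least 50 normalized read counts and no overlap between the groups were those of Gm47283 (0.76) and Pdlim4 (0.74). Ifngr1, a chain of the interferon-gamma receptor, rose by 0.65, Tnfaip3, a brake on NF-kappaB signalling, by 0.62, Dusp2, a phosphatase of MAP kinases, by 0.54, Gpr65, an acid-sensing receptor, by 0.53, and the receptor P2ry10 by 0.57 on the log2 scale (limma). Ly6c1 (0.60), whose reads could be shared with its near-identical neighbour Ly6c2, also rose. Gm47283 is annotated on chromosome Y (90784738 to 90816464), where Ddx3y averaged 3.47 normalized read counts and Uty 0.839 against 829 for Xist, so the origin of its 672 is uncertain. Ybx3, a cold shock domain protein that binds RNA, fell by 1.55 and the fatty acid binding protein Fabp5 by 0.86. The calls of Tnfaip3 and P2ry10 were lost without control 1 (0.55 and 0.47) or control 2 (0.59 and 0.63) or perampanel 2 (0.52 and 0.34). Those of Ifngr1 and Gpr65 were lost without control 2 (0.58 and 0.47), of Ifngr1 (0.46) and Gm47283 (0.49) without perampanel 2, of Fabp5 without control 1 (-0.66) or perampanel 2 (-0.83), and of Pdlim4 without control 3, perampanel 1 or perampanel 3 (0.60 to 0.66). With DESeq2, Dusp2 (0.53), P2ry10 (0.61) and Gm47283 (0.81) did not pass, and Fabp5 had no adjusted p.

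In the remaining lists few genes passed. Calcium signalling (25 genes, none called, 0 adjusted over the list alone) had a mean of 0.06 and was called by camera (adjusted p = 0.0450, and adjusted p = 0.333 with an estimated correlation), a call lost without control 1, control 3 or perampanel 1. Germinal centre and plasma cell markers (6 genes, none called, and 1, the antibody gene Ighg1 at -1.52, adjusted over the list alone) had a mean of -0.42 (camera adjusted p = 0.0427, and adjusted p = 0.333 with an estimated correlation), a call lost without control 2, control 3, perampanel 1 or perampanel 3. Camera did not call proinflammatory cytokines (0.0516, with Tnfaip3 the 1 of 8 that rose, and 1 adjusted over the list alone), integrins and adhesion (0.142), unfolded protein response (0.233), dendritic cells (0.406), cholesterol synthesis (0.572), Th1 and Th17 genes (0.572), actin cytoskeleton and migration (0.722), apoptosis (0.743), ribosomal proteins (0.892) or natural killer cells (0.942), the numbers being adjusted p-values. The mean and median had opposite signs in apoptosis (-0.07 and 0.0038) and ribosomal proteins (-0.0048 and 0.0034). Marker lists of myeloid, stromal, endothelial, epithelial, muscle, fat and red blood cells had fewer than 5 tested genes each and were not tested. Of the 5 marker lists tested, only the dendritic list separated the groups in its score (-0.18, exact permutation p = 0.1). That score rests on 5 of 16 markers and leaves out Zbtb46, Itgax and Xcr1, which had too few reads to be tested.

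In the authors' deposited table, 50 genes had an adjusted p under 0.05, 31 higher and 19 lower under perampanel. Of these 50 genes of the authors' deposited table, 48 were among the 100 called here, all 48 in the same direction. The authors' deposited table gives an adjusted p for 3018 genes only, with a mean of at least 108 normalized read counts, and 66 of the 100 genes have one. In the authors' deposited table Rrm2 and Tyms have no adjusted p.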

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

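The edgeR test, TMM scaling and thinning were chosen after the result was seen. The 32 called named genes kept their direction in all 320 values under 10 alternatives each, 50 of those values missed the threshold, and DESeq2 gave no adjusted p for 8 more. DESeq2 called 18 of the 32. All 100 called genes that could be tested kept their sign in every setting except 2 under quantile normalization. The count of changed genes was 179 with no filter, 162 at an adjusted p under 0.1, 31 with a change of at least 1 on the log2 scale, 50 with DESeq2 (28 higher and 22 lower), and 44 to 113 with 1 library left out, lowest without control 1 (44) and control 2 (55). Changed genes within lists, 23 of 416, became 47 with no filter, 35 at an adjusted p under 0.1, 7 with a change of at least 1, 15 with DESeq2, 35 with the leading residual component, and 14 to 33 with 1 library left out. The thresholds act by the genes they admit. A filter at a mean of at least 50 gave 92 changed genes, 78 of them among the 100, so a filter can also change the calls of genes already tested. For the filters, DESeq2, the residual component and the omissions the cause was not tested. Called lists, 14 of 27, fell to 1 with an estimated correlation, 0 with fry (5 at an unadjusted p under 0.05) and 9 with thinned libraries, where the cause was not tested, and ranged from 9 to 14 with 1 library left out, with 9 without control 1 and 9 without perampanel 3. Marker lists that separated the groups numbered 1 to 2 with 1 library left out. Without control 3 or perampanel 3 the fold change of Ccr7, not called, turned positive (range -0.11 to 0.011), as did that of Klf2 to negative without perampanel 2 (-0.012 to 0.089). With the replicate number as a block, 103 genes (89 of the 100) and 13 lists were called, and 4 named genes lost their call, Trac, Tcf7 and Hspa8 among them. Whether the numbers pair the mice cannot be told. Same-numbered libraries correlated at only 0.033, 0.033 and 0.016 in their deviations, yet each library correlated best with its own number, a hint from the data only. Depth limits the genes with few reads, and 40.9% of simulated changes of 0.5 were recovered.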

Other observations

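The gene families in the next paragraph, the ratio of Cd4 to Cd8a, and the tests on B cells and on tissue handling were chosen after the results were seen.

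Several gene families, defined by name, were examined beside the lists described so far. All 6 chaperonin subunits had negative fold changes (mean -0.19), as did 27 of 38 proteasome subunits (-0.09) and 55 of 77 mitochondrial ribosomal proteins (-0.10), with none called singly by limma. Among 17 heat shock protein genes 4 fell, Hsp90aa1 and Hspa8, already described, with Hsp90ab1 (-0.22) and the mitochondrial chaperone Hspd1 (-0.51). Of 13 tubulin genes 1 fell, Tuba1b (-0.39). Of 20 histone genes 2 fell, the variant gene H2afz (-0.60) and Hist1h2ae (-2.24), and 8 of the 20 had a positive fold change. Of 13 mitochondrially encoded mRNAs 3 rose, mt.Co1, mt.Nd2 and mt.Nd5, with a family mean of 0.07 that shrank to 0.016 under quantile normalization. Klf3, a repressor of the Kruppel-like family, rose by 0.40. None of these families passed camera with an estimated correlation (adjusted p from 0.0861 to 0.320), and their mean signs held under quantile, TMM and thinned scaling.

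Levels of T and B lineage genes were set side by side. Cd4 averaged 1127 and Cd8a 163 normalized read counts, and the B cell genes Ighm 437 and Cd79a 28.4, levels of different genes that give no cell shares. The ratio of Cd4 to Cd8a was 5.92 ± 0.858 in controls and 8.21 ± 0.801 under perampanel (SD, n = 3 each). Every perampanel library lay above every control, but 14.1% of all tested genes also did not overlap, against 10% by chance. The other CD8 chain gene, Cd8b1, differed less, at 205 ± 12.4 in controls and 186 ± 8.71 under perampanel. Cd8a itself did not pass over all genes (log2 -0.36, limma adjusted p = 0.130). The labels name lymphocytes of the node and no sort.

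The lower cell cycle list was set against depth, a single library and cell makeup. Thinning every library to the same reads left a mean of -1.19, which argues against depth as the cause. Leaving out 1 library at a time left at most -0.71, without perampanel 3, so no single library carries the whole fall, although that library holds much of it. Fewer B lineage cells remain open: B cell markers had a mean of -0.24 ± 0.18 (SE over 8 genes), low in reads and uneven among controls, and germinal centre and plasma cell markers -0.42 ± 0.23 (6 genes, camera adjusted p = 0.0427, and adjusted p = 0.333 with an estimated correlation), lowest in perampanel 3 (-0.46). Fewer dividing cells under the drug may explain the pattern, a hypothesis that these data on mixed cells cannot separate from a change in makeup.

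The higher glucocorticoid list could reflect hormone exposure, handling or a larger share of resting T cells. Members not tied to resting T cells had a mean of 0.11 ± 0.15 (SE over 3 genes, Fkbp5, Per1 and Sgk1), which leaves exposure open. Handling genes had a mean of -0.056 ± 0.064 (SE over 13 genes), too close to 0 to exclude handling. A resting state was not tested, and the treatment itself stays open.

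The higher interferon-gamma list rests largely on perampanel 2: without it the mean fell from 0.20 to 0.087, under the bound set for a pattern carried by 1 library. The camera call at the preset correlation was kept in all 6 omissions (adjusted p = 0.0329 without perampanel 2) but is lost with an estimated correlation (adjusted p = 0.401). The list mean of perampanel 3 (0.094) lay above the controls (-0.17 to -0.018), and that of perampanel 1 (-0.12) lay among them. A strong response in 1 mouse may account for much of the mean, and a smaller difference in the group stays open.

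Over the 10 splits of the 6 samples into 3 and 3, 1 gave as many called genes, the real one, with 100 by limma against 0 in the highest other, where 324 to 485 genes had an unadjusted p under 0.05 against 847. Likewise 1 of the 10 gave as many called lists, with 14 against 11 in the highest other. The cell cycle list was called by camera at its preset correlation in 7 of the 9 other splits, so that p-value alone does not set the real grouping apart. With 10 splits no share under 0.05 can be reached.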
